A study of Homo sapiens with 8 samples.

How the data were processed

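RNA from MDA-MB-231 and its lung-metastatic derivative MDA231-LM2 was analysed in 8 libraries, made after mRNA enrichment from total RNA according to the labels. The labels place 2 libraries (numbers 2 and 3) in each of 4 groups, control and shTAF7 hairpins in each line, and a single hairpin (number 3 in the titles) was used against TAF7. The labels do not say that the libraries of a group are separate cultures, so p-values measure only the spread between libraries. The deposited read counts per gene were whole numbers without normalization, and the submitters' processing notes name STAR 2.7.10a and the human genome build hg19 without saying for which step. The program that counted reads, the strand setting and the gene annotation are not given in the sources used here. The deposited FPKM values were scaled by the authors to gene length and to the reads counted in genes, as judged from the values. For the 2915 genes checked, the ratio of count to FPKM followed the library totals within 0.0559%. The count table held 61552 genes by Ensembl identifier, of which 94.8% were found in GENCODE release 29, from which gene type, chromosome, GC content and transcript length were taken.

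Library totals and genes detected are given at the start of the report. With n = 2 libraries per group, 4 residual degrees of freedom were shared by all groups. Genes were filtered with edgeR's filterByExpr, which left 15923 genes, and counts were scaled with TMM. A quasi-likelihood model with a mean for each group was fitted to all 8 libraries (R 4.3.3, edgeR 4.0.16), and 4 comparisons were tested: knockdown against control in MDA-MB-231, the same in LM2, LM2 against MDA-MB-231 controls, and the difference between the knockdown effects (interaction). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM means and SD were computed from the library totals over the tested genes, multiplied by the TMM factors. Where a group had no count of a gene, the fold change was bounded with a floor of 3 counts per library, and where it had 1 to 3 counts, a ratio with a 95% interval was computed. These intervals and floors cover counting error only.

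Before the data were examined, 35 gene lists were fixed, and 34 with at least 5 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over lists. Each list was also tested with an estimated correlation and with fry. Counts of called members are given at the adjustment over all genes and, as stated, adjusted over the list alone. The rule for named genes was also fixed then. It named TAF7 and TFIID subunits, the 8 highest and 8 lowest called genes of a comparison by log2 fold change with a mean of at least 5 CPM and no overlap between the groups, up to 4 called members of each called list, 6 genes per direction changed in both lines and 4 per sign of the interaction. Genes that the rule picked but whose call ended when a library was left out are mostly not discussed. LCP1, CD74, KRT8 and KRT18 were singled out after their values were seen.

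The pipeline was tested on simulated data with 15923 genes and 50 changed genes per fold and comparison. At folds of 1.25, 1.5, 2 and 4 it recovered 38%, 50%, 86% and 88% in MDA-MB-231, 50%, 56%, 76% and 92% in LM2, 38%, 74%, 74% and 86% between controls, and 18%, 46%, 70% and 88% for the interaction. Unchanged genes made up 6.43%, 3.52%, 5.56% and 9.02% of calls in that order. A shifted list was called by camera with an adjusted p of 4.3e-64, and 0 of the other lists were called. Genes were simulated independently and lists drawn at random, so this could not show false list calls from correlation between genes. Correlations estimated in the data reached 0.68 for ribosomal proteins and 0.90 for mitochondrially encoded mRNAs. In the data 25.6% to 64.4% of genes were called in a comparison, far more than were changed in the simulation.

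The alternatives tried were RLE size factors, DESeq2 1.42.0, no low-count filter, only the 4 libraries of a comparison, the replicate number as a block, each library left out, limma-trend on log2 FPKM with a pseudocount of 1, a minimum log2 fold change of 1, and the other list tests. Offsets for GC content and transcript length, from natural splines with 5 degrees of freedom, were added after seeing the data. The fit of each library also held a constant, so the offsets rescaled the libraries against each other as well. Bootstrap intervals used 1000 draws of list members, and random lists matched on mean expression were drawn 10000 times. Windows of 40 neighbouring genes (at least 20 at chromosome ends) with a mean of at least 10 CPM were compared with 1000 shuffles of gene order.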

Results

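Messenger RNA was sequenced in 8 libraries from MDA-MB-231, a triple-negative breast cancer cell line, and from MDA231-LM2 (LM2 below), a derivative of that line selected for metastasis to the lung. Each line carried either a control hairpin or a short hairpin RNA against TAF7 (shTAF7), which encodes a subunit of TFIID, the general transcription factor that recruits RNA polymerase II to promoters. Each of the 4 groups held 2 libraries, numbered 2 and 3 in the labels, and the stated aim was to find transcripts controlled by TAF7. Total counts in genes were 18918573 and 17663626 for the MDA-MB-231 control, 17217776 and 20292291 for MDA-MB-231 shTAF7, 17633474 and 17295627 for the LM2 control, and 18682954 and 20285659 for LM2 shTAF7. At these depths 1 read in a library corresponded to between 0.0488 and 0.0583 CPM (counts scaled by the library total over tested genes and the TMM factor), and 15923 genes had enough reads to be tested. The LM2 control libraries stood apart from the other groups in composition. Reads were found in 24762 and 24490 genes there, against 22296 to 23434 in the other 6 libraries. Genes for lincRNA and antisense RNA took 0.709% ± 0.0165 of their counts (SD, n = 2), against 0.569% ± 0.0154 in LM2 shTAF7, 0.524% ± 0.00256 in the MDA-MB-231 control and 0.516% ± 0.0336 in MDA-MB-231 shTAF7. Mitochondrially encoded genes took 5.86% ± 0.131 of the LM2 control counts and 5.13% ± 0.785, 3.68% ± 0.402 and 4.19% ± 0.964 in the same order. In what follows, log2 fold changes are given ± the standard error of the fit with n = 2 libraries per group, CPM values are given ± SD, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

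TAF7 itself (ENSG00000178913) was lower in every shTAF7 library than in every control library of the same line. It had 3446 and 3300 counts in the MDA-MB-231 control and 1845 and 2160 in MDA-MB-231 shTAF7, which corresponded to 181.9 ± 3.84 and 106.5 ± 1.57 CPM. In LM2 it had 3548 and 3527 counts in the control and 2549 and 2809 in shTAF7, or 195.9 ± 0.874 and 145.3 ± 4.26 CPM. TAF7 thus fell to 58.5% of its control level in MDA-MB-231 (log2 fold change -0.77 ± 0.07, edgeR adjusted p = 4.0e-12) and to 74.2% in LM2 (-0.43 ± 0.07, edgeR adjusted p = 8.4e-07, and -0.55 with limma on FPKM, which used no TMM). The difference between the lines passed the interaction test (0.34 ± 0.09, edgeR adjusted p = 0.00544), though not without MDA-MB-231 control replicate 3 (0.33, adjusted p = 0.0513). TAF7 was not called between the control libraries of the 2 lines (0.11 ± 0.07, edgeR adjusted p = 0.152), though it passed with limma on FPKM (0.13, adjusted p = 0.0178). Its sign turned with GC and length offsets (-0.0761, edgeR adjusted p = 0.254), where the median of all genes was -0.08.

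Among the other TFIID subunits, TAF1, the scaffold of the complex that binds TAF7, fell in both lines, by 0.56 ± 0.09 on the log2 scale in MDA-MB-231 and by 0.53 ± 0.11 in LM2 (edgeR adjusted p = 1.0e-05 and 7.4e-05). TAF9 rose in MDA-MB-231 (0.41 ± 0.08), and its paralog TAF9B rose in LM2 (0.32 ± 0.08). TAF9 in LM2 passed the test with all libraries (0.25 ± 0.07) but not without LM2 control replicate 3 (0.16, edgeR adjusted p = 0.146) or with limma on FPKM (0.12, adjusted p = 0.23). Over the 16 subunits, 2 rose, 2 fell and 12 were not called in MDA-MB-231, and 4 rose, 2 fell and 10 were not called in LM2, with the same counts adjusted over the list alone. The list as a set was not called by limma's camera test in either line (median -0.06, adjusted p = 0.437, and median 0.11, adjusted p = 0.556).

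**Figure D1:**
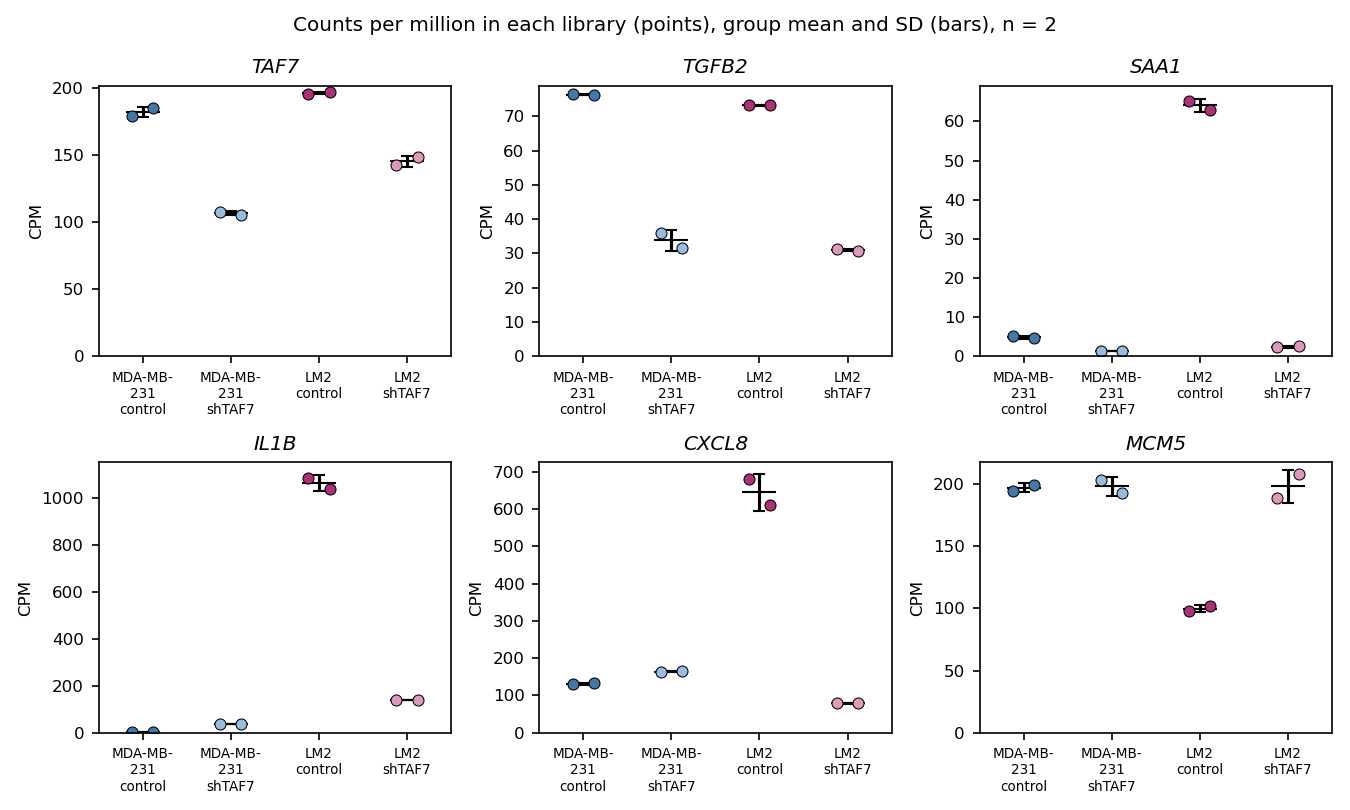
CPM of TAF7, TGFB2, SAA1, IL1B, CXCL8 and MCM5 in each library (points), with the mean and SD of each group (bars, n = 2). TAF7 and TGFB2 were lower after knockdown in both lines, IL1B rose from 4.99 to 36.8 CPM in MDA-MB-231 and fell from 1064 to 140.2 CPM in LM2, and MCM5 was near 198 CPM in every group but the LM2 control, where it was at 99.7 CPM.

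The comparison of shTAF7 with control in MDA-MB-231 addressed which transcripts change with TAF7 in the parental line. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, rose 7.38-fold, from 4.99 ± 0.00899 to 36.8 ± 0.129 CPM (log2 fold change 2.88 ± 0.11, n = 2). BCL2A1, an antiapoptotic member of the BCL2 family, rose from 9 to 202 counts over the 2 libraries of each group (4.43 ± 0.32). Among the genes that fell, TGFB2, which encodes transforming growth factor beta 2, went to 44.1% of its control level (-1.18 ± 0.08), and CCNE2, which encodes cyclin E2, fell by 1.30 ± 0.14 on the log2 scale. The edgeR adjusted p-values of these genes lay between 4.9e-25 for IL1B and 2.0e-09 for CCNE2.

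Other large increases in MDA-MB-231 were those of ESM1, a secreted proteoglycan (2.38 ± 0.33), and HCLS1, an actin-binding adaptor protein (1.64 ± 0.19). Other large decreases were those of MFAP3, a microfibril-associated protein (-1.49 ± 0.08), FLG, which encodes filaggrin (-1.40 ± 0.15), CDK15 (-1.22 ± 0.12) and VGLL3, a cofactor of TEAD transcription factors (-1.16 ± 0.16). SAA1, an acute-phase protein, fell by 1.91 ± 0.22, but reads of SAA1 and its near-identical neighbour SAA2 cannot be told apart with certainty in these counts.

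Camera called several lists of genes fixed in advance higher in MDA-MB-231, although many of their members were not called. Of 23 NF-kB cytokines and targets, 14 rose, 2 fell and 7 were not called (15 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 0.32. They included IL1A (1.54 ± 0.26) and ICAM1, an adhesion molecule (1.18 ± 0.12), and camera called the list (adjusted p = 1.9e-05, adjusted p = 0.138 with an estimated correlation). Of 34 interferon-stimulated genes, 14 rose, 1 fell and 19 were not called (18 and 1 adjusted over the list alone), among them the RNA sensor IFIH1 (0.82 ± 0.15) and IFI44 (0.74 ± 0.09). For interferon-stimulated genes the median was 0.27 (camera adjusted p = 0.000342, adjusted p = 0.138 with an estimated correlation). Of 33 hypoxia and glycolysis genes, 16 rose and 17 were not called, with the same counts adjusted over the list alone. Carbonic anhydrase CA9 (1.47 ± 0.25), the mitophagy receptor BNIP3 (0.65 ± 0.07) and PFKFB4 (0.58 ± 0.09) were among them. For hypoxia and glycolysis genes the median was 0.20 (camera adjusted p = 6.7e-08, adjusted p = 0.557 with an estimated correlation). Of 15 replication-dependent histone genes, 5 rose and 10 were not called, also adjusted over the list alone, with H1-2 at 1.05 ± 0.08 and H2BC12 at 0.61 ± 0.08. For histones the median was 0.55 (camera adjusted p = 0.00318, adjusted p = 0.193 with an estimated correlation). Only 15 of the 22 histone genes listed had enough reads, and how evenly mRNA enrichment kept their transcripts in the 4 groups was not examined.

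Ribosomal proteins, nuclear oxidative phosphorylation and mitochondrially encoded mRNAs were also called higher in MDA-MB-231 shTAF7. Of 77 cytosolic ribosomal protein genes, 62 rose and 15 were not called (66 rose adjusted over the list alone), with RPS29 at 0.54 ± 0.08 and RPL13A at 0.48 ± 0.08, and the list took 7.01% ± 0.114 of counts against 5.78% ± 0.102 in the control. Its median was 0.32 (camera adjusted p = 6.0e-21, adjusted p = 0.635 with an estimated correlation), and reads of these genes can be shared with their many pseudogenes. Of 45 nuclear genes for oxidative phosphorylation, 23 rose and 22 were not called (24 rose and 1 fell adjusted over the list alone), including the cytochrome c oxidase subunits COX8A (0.54 ± 0.11) and COX5B (0.49 ± 0.08). That list had a median of 0.22 (camera adjusted p = 2.6e-06, adjusted p = 0.638 with an estimated correlation). The 13 mitochondrially encoded mRNAs, of which 4 rose and 9 were not called (8 rose adjusted over the list alone), had a median of 0.25 (camera adjusted p = 0.0331, adjusted p = 0.807 with an estimated correlation). Their call was lost without control replicate 3 (median 0.10, adjusted p = 0.503) or shTAF7 replicate 3 (median 0.0105, adjusted p = 0.905), with limma on FPKM (0.208) and with GC and length offsets (0.109).

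In MDA-MB-231, 4 lists were called lower. Of 23 targets of the YAP and TEAD transcription regulators, 16 fell, 1 rose and 6 were not called (17 fell and 1 rose adjusted over the list alone), with a median of -0.29. ANKRD1 (-1.03 ± 0.07), AMOTL2 (-0.61 ± 0.08) and AJUBA (-0.58 ± 0.07) were among them beside TGFB2 (camera adjusted p = 5.1e-08, adjusted p = 0.138 with an estimated correlation). Of 26 TGF-beta targets, 11 fell, 3 rose and 12 were not called (12 fell and 4 rose adjusted over the list alone), including SMAD6 (-0.74 ± 0.13), the basement membrane collagen COL4A1 (-0.69 ± 0.08) and the cytokine IL11 (-0.66 ± 0.07). Its median was -0.14 (camera adjusted p = 0.029, adjusted p = 0.638 with an estimated correlation, and 0.0588 with limma on FPKM). Of 32 ribosome biogenesis and MYC target genes, 12 fell, 1 rose and 19 were not called (13 and 1 adjusted over the list alone), with DDX21 at -0.72 ± 0.08, HSPD1 at -0.54 ± 0.07 and WDR43 at -0.52 ± 0.07. For ribosome biogenesis the median was -0.10 (camera adjusted p = 6e-04, adjusted p = 0.635 with an estimated correlation). Of 40 G1/S and DNA replication genes, 14 fell, 3 rose and 23 were not called, also adjusted over the list alone, with the replicative helicase subunit MCM4 at -0.36 ± 0.07. For G1/S genes the median was -0.08 (camera adjusted p = 0.00916, adjusted p = 0.722 with an estimated correlation). That call was lost without shTAF7 replicate 3 (camera adjusted p = 0.146).

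The 19 genes of a published lung metastasis signature, which was drawn from derivatives of MDA-MB-231 such as LM2, were called higher by camera after knockdown in the parental line. In it 7 rose, 2 fell and 10 were not called (8 and 3 adjusted over the list alone), and the matrix proteins TNC (0.67 ± 0.08) and LTBP1 (0.49 ± 0.08) and the enzyme KYNU (0.48 ± 0.08) rose. Its median was 0.21 (camera adjusted p = 0.00916, adjusted p = 0.635 with an estimated correlation, and 0.0561 with GC and length offsets, where the median was 0.027). Lists that were not called had medians between -0.12 and 0.14. They were the general transcription factors, MHC class I presentation, mesenchymal, epithelial, luminal and basal markers, endothelial and fibroblast markers, matrix proteases, integrins, G2/M and mitosis, p53 targets, apoptosis regulators, ATF4 and amino acid response, ER chaperones, heat shock proteins, cholesterol biosynthesis, immediate early genes, MAPK output and EGFR ligands, NRF2 targets, splicing factors and common reference genes. Heat shock proteins (-0.10) and G2/M genes (-0.09) came close, and were called lower without shTAF7 replicate 2 (camera adjusted p = 0.00511 and 0.00672), without LM2 control replicate 3 (0.0403 for both) and without either LM2 shTAF7 library (0.0423 and 0.0243 without replicate 2, 0.0429 and 0.0246 without replicate 3). Both were also called with limma on FPKM (0.041 and 0.035), with GC and length offsets (0.00898 and 0.0334) and without the low-count filter (0.0188 and 0.0282). The G2/M list was called with RLE size factors (0.0492), and the NRF2 targets with GC and length offsets (0.011). None of these gained calls held with an estimated correlation.

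In all, 2013 genes rose and 2057 fell in MDA-MB-231 at an edgeR adjusted p under 0.05, of which 141 rose and 77 fell at least 2-fold. The number rested on single libraries, with 897 higher and 1134 lower without control replicate 2, 1080 and 1199 without control replicate 3, and 1274 and 1088 without shTAF7 replicate 3. None of the 12 lists called by camera was called with estimated correlations (0 lists, against 4 at an unadjusted p under 0.05 and 11 by fry). The median of a called list in MDA-MB-231 moved more than 1.5 times without MDA-MB-231 control replicate 2 for mitochondrially encoded mRNAs (0.37) and TGF-beta targets (-0.00171). Without MDA-MB-231 control replicate 3 it moved so for mitochondrially encoded mRNAs (0.10) and TGF-beta targets (-0.22). Without MDA-MB-231 shTAF7 replicate 2 it moved so for G1/S genes (-0.15), hypoxia and glycolysis (0.12), mitochondrially encoded mRNAs (0.43) and TGF-beta targets (-0.0766). Without MDA-MB-231 shTAF7 replicate 3 it moved so for G1/S genes (-0.043) and mitochondrially encoded mRNAs (0.0105). With limma on FPKM the medians in MDA-MB-231 moved as far for interferon-stimulated genes (0.13), the lung metastasis signature (0.0933) and histones (0.34). With GC and length offsets the medians in MDA-MB-231 moved as far for the lung metastasis signature (0.027), G1/S genes (-0.12), ribosome biogenesis (-0.20) and mitochondrially encoded mRNAs (0.15).

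The comparison of shTAF7 with control in LM2 addressed the same question in the metastatic derivative, where all 23 tested NF-kB cytokines and targets fell. CXCL8, which encodes the chemokine interleukin-8, fell from 645 ± 49.2 to 79.0 ± 0.691 CPM (log2 fold change -3.03 ± 0.07, n = 2), IL6 fell from 83.7 ± 4.37 to 10.2 ± 0.0551 CPM (-3.04 ± 0.10), and complement C3 fell to 4.59% of its control level (-4.45 ± 0.11). GDF15, a stress-induced cytokine, fell to 2.75% (-5.19 ± 0.18). MCM5, a subunit of the replicative helicase, rose by 0.99 ± 0.07, and IDI1, an enzyme of cholesterol synthesis, by 1.12 ± 0.07. The edgeR adjusted p-values of these genes were at most 4.0e-16.

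Further large decreases in LM2 were those of SAA1 (-4.70 ± 0.13, uncertain for the reason given above), IGFN1 (-3.60 ± 0.17) and the cytokine IL24 (-3.06 ± 0.17). VAMP8, a vesicle fusion protein, fell from 17 counts over the 2 control libraries to 1, a ratio of 17.3 (95% counting interval 2.72 to 725). Large increases were those of the protocadherin PCDH7 (2.01 ± 0.16), the transcription factor NKX2-1 (1.86 ± 0.22), the nuclear receptor NR4A1 (1.75 ± 0.18), the peptide hormone APLN (1.45 ± 0.16), SNCAIP (1.43 ± 0.16) and the growth factor binding protein IGFBP3 (1.37 ± 0.07).

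All 23 tested NF-kB cytokines and targets fell in LM2, also adjusted over the list alone, with a median of -1.72. Beside CXCL8 and IL6, IL1A (-3.87 ± 0.31) and CCL20 (-3.24 ± 0.21) were the most changed, and the call held with an estimated correlation (camera adjusted p = 4.0e-28, adjusted p = 0.00797 with an estimated correlation). Of 34 interferon-stimulated genes, 24 fell, 1 rose and 9 were not called (26 and 1 adjusted over the list alone), including the antiviral genes IFIT2 (-2.19 ± 0.09), OASL (-1.60 ± 0.13) and MX2 (-1.50 ± 0.28). This call held as well (median -0.76, camera adjusted p = 3.0e-10, adjusted p = 0.0277 with an estimated correlation). Of 18 MHC class I presentation genes, 11 fell and 7 were not called (11 fell and 1 rose adjusted over the list alone), with the peptide transporter TAP1 at -0.80 ± 0.13, the immunoproteasome subunit PSMB9 at -0.88 ± 0.15 and HLA-B at -1.25 ± 0.08, although reads of HLA genes can be shared between them. For MHC class I genes the median was -0.35 (camera adjusted p = 0.00065, adjusted p = 0.31 with an estimated correlation).

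Of 31 ATF4 and amino acid response genes, 26 fell, 2 rose and 3 were not called in LM2, also adjusted over the list alone. CTH, an enzyme of cysteine synthesis (-2.30 ± 0.10), the secreted hormone STC2 (-2.13 ± 0.28), SESN2 (-1.71 ± 0.09) and the stress transcription factor DDIT3 (-1.56 ± 0.13) were among them. For ATF4 genes the median was -0.62 (camera adjusted p = 5.4e-16, adjusted p = 0.0681 with an estimated correlation). Of 27 immediate early genes, 14 fell, 6 rose and 7 were not called (15 and 7 adjusted over the list alone), with KLF4 at -1.33 ± 0.08 and IER3 at -1.30 ± 0.07, while NR4A1 of the same list rose. For immediate early genes the median was -0.42 (camera adjusted p = 0.00264, adjusted p = 0.131 with an estimated correlation). Of 27 genes of MAPK output and EGFR ligands, 13 fell, 3 rose and 11 were not called, also adjusted over the list alone. The EGFR ligands AREG (-1.65 ± 0.15), EREG (-0.99 ± 0.08) and HBEGF (-0.92 ± 0.07) and the gene PHLDA1 (-0.79 ± 0.07) fell. For MAPK output the median was -0.18 (camera adjusted p = 0.000701, adjusted p = 0.31 with an estimated correlation).

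Lists for mesenchymal markers, integrins, matrix proteases, basal markers and histones were lower in LM2 shTAF7, with exceptions among their members. Weakly expressed genes as a whole fell there, with a median of -0.39 at up to 1 CPM, -0.23 at 1 to 3 CPM and -0.11 at 3 to 10 CPM. No list called lower in LM2 was compared with random lists matched on expression, so how far these lists follow that trend was not tested. Of 25 mesenchymal markers, 14 fell, 1 rose and 10 were not called (14 and 2 adjusted over the list alone), including PDGFRB (-1.75 ± 0.26), the gelatinase MMP2 (-1.45 ± 0.29) and the collagens COL6A1 (-1.07 ± 0.07) and COL5A1 (-0.94 ± 0.09). For mesenchymal markers the median was -0.35 (camera adjusted p = 0.000573, adjusted p = 0.18 with an estimated correlation). Of 14 integrins, 8 fell, 1 rose and 5 were not called (11 and 1 adjusted over the list alone), with ITGA1 at -1.26 ± 0.10 and ITGB2 at -1.03 ± 0.13. For integrins the median was -0.38 (camera adjusted p = 0.000573, adjusted p = 0.216 with an estimated correlation). Of 28 matrix proteases and invasion genes, 11 fell, 5 rose and 12 were not called (11 and 6 adjusted over the list alone). ADAMTS6 (-1.37 ± 0.10) and the urokinase gene PLAU (-1.02 ± 0.07) fell, whereas the collagenase MMP1, a member of the lung metastasis signature, rose from 246 ± 7.97 to 507.5 ± 15.8 CPM (1.04 ± 0.07). That list had a median of -0.13 (camera adjusted p = 0.0249, adjusted p = 0.31 with an estimated correlation). With GC and length offsets its median turned to 0.05, below the median of all genes (0.08). Camera still called the list lower there (adjusted p = 0.0428, 0.34 with an estimated correlation). Of 13 basal and myoepithelial markers, 6 fell, 1 rose and 6 were not called (7 and 1 adjusted over the list alone), with the laminin chain LAMA3 (-0.72 ± 0.09) and MYLK (-0.91 ± 0.10) lower. Its median was -0.19 (camera adjusted p = 0.022, adjusted p = 0.307 with an estimated correlation), and the call was lost without shTAF7 replicate 3 (0.0614), with limma on FPKM (0.0843) and with GC and length offsets (0.0552). Of 15 histone genes, 8 fell and 7 were not called (9 fell and 1 rose adjusted over the list alone), with H2BC21 at -1.34 ± 0.27. For histones the median was -0.62 (camera adjusted p = 0.0249, adjusted p = 0.214 with an estimated correlation). The histone call was lost without control replicate 2 (0.0578), without shTAF7 replicate 2 (0.0556) and with limma on FPKM (0.0843).

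The G1/S, G2/M and cholesterol biosynthesis lists were called higher in LM2. Of 40 G1/S and DNA replication genes, 35 rose and 5 were not called (37 rose adjusted over the list alone), including the histone mRNA binding protein SLBP (0.99 ± 0.07), the replication-coupled methylation factor UHRF1 (0.81 ± 0.07) and the sliding clamp PCNA (0.75 ± 0.07). For G1/S genes the median was 0.43 (camera adjusted p = 4.5e-16, adjusted p = 0.131 with an estimated correlation). Of 39 G2/M and mitosis genes, 30 rose, 1 fell and 8 were not called (31 and 1 adjusted over the list alone). KIF20A (0.66 ± 0.07), ANLN (0.63 ± 0.07) and CKS2 (0.45 ± 0.07) rose and the hyaluronan receptor HMMR fell (-0.65 ± 0.10). For G2/M genes the median was 0.29 (camera adjusted p = 7.7e-09, adjusted p = 0.138 with an estimated correlation). Of 25 cholesterol biosynthesis genes, 22 rose and 3 were not called, also adjusted over the list alone, with HMGCS1 at 1.05 ± 0.08. For cholesterol genes the median was 0.59 (camera adjusted p = 2.8e-12, adjusted p = 0.0681 with an estimated correlation).

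Ribosomal proteins, nuclear oxidative phosphorylation, ribosome biogenesis, general transcription factors, splicing factors and heat shock proteins were also called higher in LM2 shTAF7. Highly expressed genes as a whole rose there, with a median of 0.14 at 100 to 300 CPM and 0.27 above 300 CPM. Of all lists, only the ribosomal proteins were compared with random lists matched on expression. Of 77 ribosomal protein genes, 66 rose and 11 were not called (71 rose adjusted over the list alone), with RPL4 at 0.52 ± 0.08, RPL38 at 0.50 ± 0.07 and RPL18 at 0.49 ± 0.08. For ribosomal proteins the median was 0.33 (camera adjusted p = 1.3e-14, adjusted p = 0.351 with an estimated correlation). Of 45 nuclear oxidative phosphorylation genes, 33 rose and 12 were not called (34 rose adjusted over the list alone), with COX8A at 0.74 ± 0.11. For oxidative phosphorylation the median was 0.29 (camera adjusted p = 8.9e-10, adjusted p = 0.31 with an estimated correlation). Of 32 ribosome biogenesis and MYC target genes, 19 rose, 2 fell and 11 were not called (20 and 2 adjusted over the list alone). BOP1 (0.56 ± 0.07), SRM (0.54 ± 0.07) and NOP16 (0.51 ± 0.08) rose while MYC itself fell (-0.56 ± 0.07). For ribosome biogenesis the median was 0.26 (camera adjusted p = 0.000112, adjusted p = 0.26 with an estimated correlation). Of 28 general transcription factor genes, 15 rose, 1 fell and 12 were not called, also adjusted over the list alone, with the polymerase subunits POLR2F (0.70 ± 0.08) and POLR2L (0.67 ± 0.07) highest. For general transcription factors the median was 0.21 (camera adjusted p = 0.000573, adjusted p = 0.323 with an estimated correlation). Of 36 splicing factors, 21 rose, 5 fell and 10 were not called (23 and 6 adjusted over the list alone), with SRSF2 at 0.73 ± 0.07 and MBNL2 at -0.75 ± 0.08. For splicing factors the median was 0.28 (camera adjusted p = 0.000573, adjusted p = 0.31 with an estimated correlation). Of 22 heat shock proteins, 13 rose, 2 fell and 7 were not called, also adjusted over the list alone, with HSPA8 at 0.79 ± 0.09 and AHSA1 at 0.59 ± 0.07 higher and HSPB8 lower (-1.79 ± 0.27). For heat shock proteins the median was 0.21 (camera adjusted p = 0.00538, adjusted p = 0.407 with an estimated correlation).

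Of 33 hypoxia and glycolysis genes in LM2, 19 rose, 4 fell and 10 were not called, also adjusted over the list alone. CA9 (1.03 ± 0.26), BNIP3 (0.61 ± 0.07) and the glycolytic enzyme TPI1 (0.57 ± 0.08) rose, whereas VEGFA, the hypoxia-induced angiogenic factor, fell from 339.1 ± 1.18 to 99.1 ± 2.52 CPM (-1.78 ± 0.07). For hypoxia and glycolysis genes the median was 0.28 (camera adjusted p = 0.000701, adjusted p = 0.351 with an estimated correlation). Of 24 common reference genes, 12 rose and 12 were not called, also adjusted over the list alone, with ACTB at 0.71 ± 0.09, VCP at 0.68 ± 0.07 and HPRT1 at 0.59 ± 0.07. For reference genes the median was 0.19 (camera adjusted p = 0.00109, adjusted p = 0.323 with an estimated correlation). Among 5 endothelial and fibroblast markers with enough reads, PDGFRB, PECAM1 (-1.70 ± 0.28) and COL1A1 (-0.85 ± 0.12) fell and 2 were not called, also adjusted over the list alone. For endothelial and fibroblast markers the median was -0.85 (camera adjusted p = 0.0166, adjusted p = 0.214 with an estimated correlation). The lists not called in LM2 were TFIID subunits, the epithelial and luminal markers, the lung metastasis signature, p53 targets, apoptosis regulators, ER chaperones, mitochondrially encoded mRNAs, YAP/TEAD targets, TGF-beta targets and NRF2 targets, with medians between -0.26 and 0.11. In the lung metastasis signature 9 genes fell, 5 rose and 5 were not called, also adjusted over the list alone. For the lung metastasis signature the median was -0.16 (camera adjusted p = 0.07). Camera called it lower in a fit to only the 4 libraries compared (adjusted p = 0.0444, 0.411 with an estimated correlation). It was also called lower without shTAF7 replicate 3 (median -0.24), a call that did not hold with an estimated correlation either.

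In all, 3478 genes rose and 3092 fell in LM2 at an edgeR adjusted p under 0.05, of which 120 rose and 844 fell at least 2-fold, and 1893 rose with limma on FPKM. The changes followed expression level, with a median of -0.39 over 2449 genes with a mean of at most 1 CPM and of 0.27 over 519 genes above 300 CPM, where the latter genes had a median of 0.05 in MDA-MB-231. By gene type the median was -0.27 for lincRNA and -0.25 for antisense genes, which took a larger share of the LM2 control libraries than of any other group, and 0.28 for processed pseudogenes. The share of calls that were higher was 52.9%. It was 32.0% with limma on FPKM, which used no TMM and where the median shift of a gene from the main fit was -0.11. With GC and length offsets the share was 68.1%, with a median shift of 0.087. Of the 23 lists called by camera, 11 higher and 12 lower, only NF-kB and interferon-stimulated genes remained called with estimated correlations, whereas fry called 28. The median of a called list in LM2 moved more than 1.5 times without LM2 control replicate 2 for matrix proteases (-0.23). Without LM2 control replicate 3 it moved so for basal markers (-0.12). Without LM2 shTAF7 replicate 2 it moved so for matrix proteases (-0.22) and common reference genes (0.30). Without LM2 shTAF7 replicate 3 it moved so for matrix proteases (-0.06) and basal markers (-0.12). With limma on FPKM the medians in LM2 moved as far for general transcription factors (0.0743), interferon-stimulated genes (-0.40), G2/M genes (0.16), heat shock proteins (0.0813), hypoxia and glycolysis (0.13), ribosomal proteins (0.20), ribosome biogenesis (0.12), oxidative phosphorylation (0.15), immediate early genes (-0.27), MAPK output (-0.29), histones (-0.34), splicing factors (0.14), common reference genes (0.0375) and endothelial and fibroblast markers (-0.37). With GC and length offsets the medians in LM2 moved as far for matrix proteases (0.0454), integrins (-0.23), MAPK output (-0.0447), common reference genes (0.28) and basal markers (-0.0447).

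**Figure D2:**
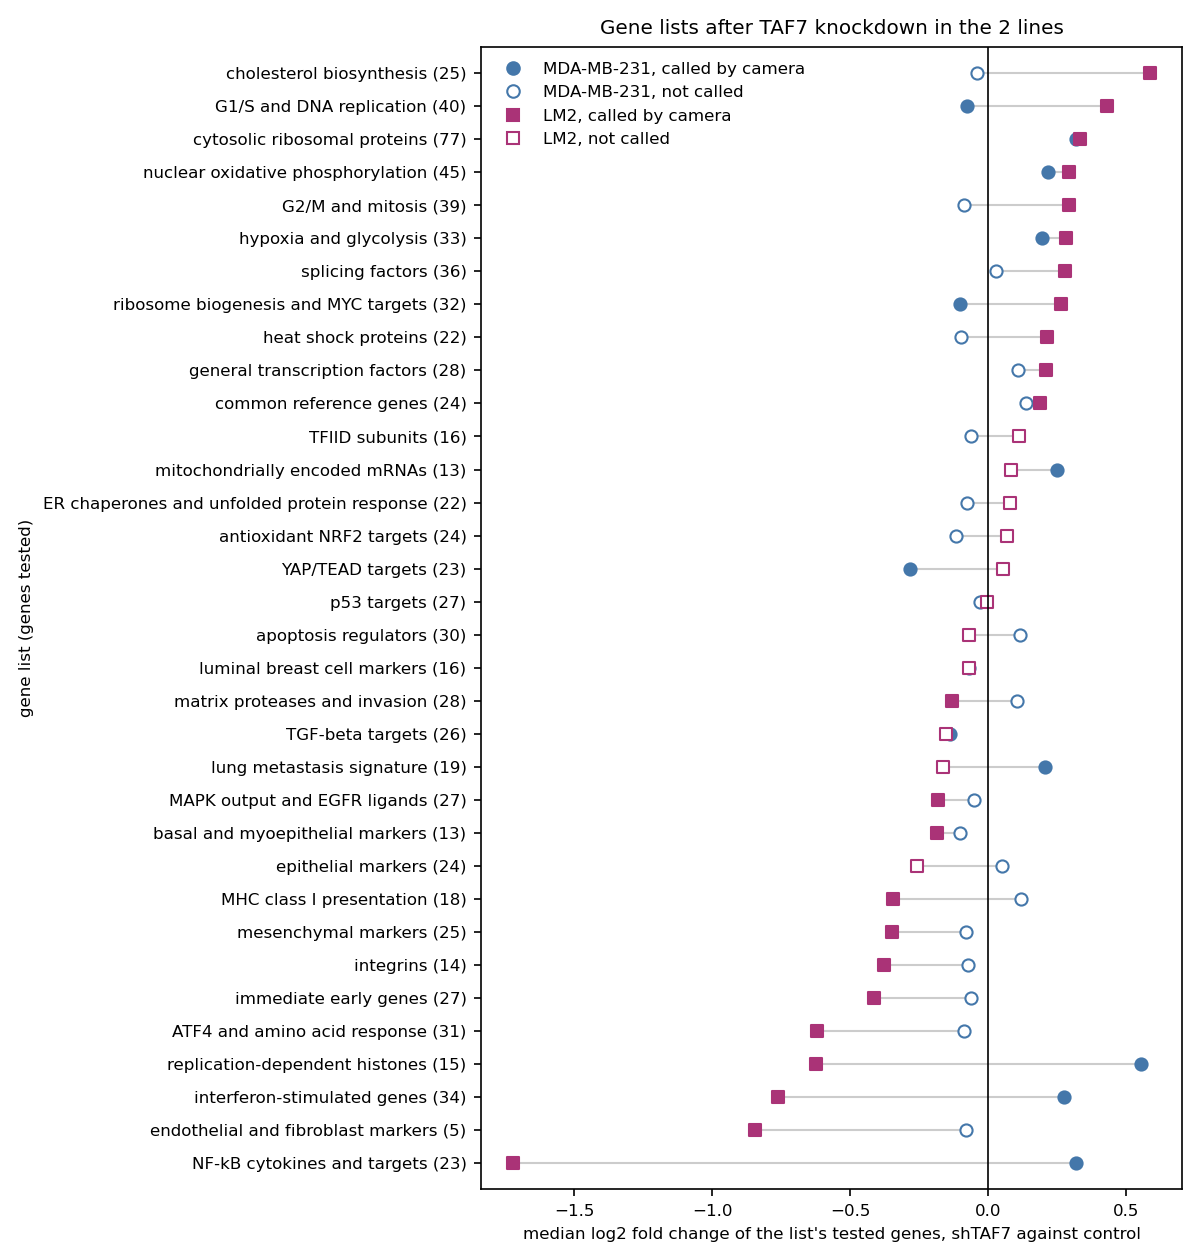
Median log2 fold change after TAF7 knockdown of the tested genes of each list in MDA-MB-231 (circles) and LM2 (squares), filled where limma's camera test called the list with a preset correlation. NF-kB cytokines and targets had medians of 0.32 and -1.72, and cytosolic ribosomal proteins 0.32 and 0.33. The median of matrix proteases in LM2 turned from -0.13 to 0.05 with GC and length offsets (0.08 over all genes), where camera still called the list lower.

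The genes changed in both lines address which transcripts change with the hairpin against TAF7 in either background. The 2 knockdown comparisons share no library, but both used the same hairpin. Changes seen in both lines therefore cannot separate an effect of TAF7 from other effects of that hairpin. DCLK1, a microtubule-associated kinase, rose 2.23-fold in MDA-MB-231 (1.16 ± 0.11) and 2.36-fold in LM2 (1.24 ± 0.08). RASD1, a Ras-related GTPase, rose by 1.18 ± 0.15 and 1.28 ± 0.09, the transcription factor SP5 by 0.91 ± 0.18 and 1.12 ± 0.17, and the retinoic acid binding protein CRABP2 by 1.47 ± 0.17 and 0.89 ± 0.14. TGFB2 fell in both (-1.18 ± 0.08 and -1.24 ± 0.08), as did VGLL3 (-1.16 ± 0.16 and -1.23 ± 0.15), MFAP3 (-1.49 ± 0.08 and -1.03 ± 0.09), the adhesion molecule AMIGO2 (-1.05 ± 0.07 and -0.98 ± 0.08) and the interleukin-7 receptor IL7R (-0.94 ± 0.09 and -1.46 ± 0.10). All of these had edgeR adjusted p-values of at most 9.96e-05 in both lines.

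In total 983 genes rose in both lines, where 440 would be shared by independent lists of these sizes, and 654 fell in both, where 399 would be. Genes that moved in opposite directions were fewer than that number, with 305 higher in MDA-MB-231 and lower in LM2 (391 for independent lists) and 313 the other way (449). Without MDA-MB-231 control replicate 2, 427 genes rose and 368 fell in both lines, without control replicate 3, 551 and 382, and without MDA-MB-231 shTAF7 replicate 3, 411 fell in both. With limma on FPKM 445 rose in both, and 341 fell in both with GC and length offsets and 435 without the low-count filter. Across all tested genes the fold changes of the lines correlated weakly (Pearson r 0.036, Spearman rho 0.15), and across the 9412 genes with a mean of at least 10 CPM somewhat more (0.21 and 0.30). Genes are not independent replicates, so these are descriptions without a test, and the first value was -0.0324 without MDA-MB-231 control replicate 2, 0.0102 without control replicate 3, 0.0937 without shTAF7 replicate 3 and 0.0092 without LM2 shTAF7 replicate 3. It was 0.0116 without the low-count filter, 0.104 with only the 4 libraries compared and 0.179 with limma on FPKM.

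**Figure D3:**
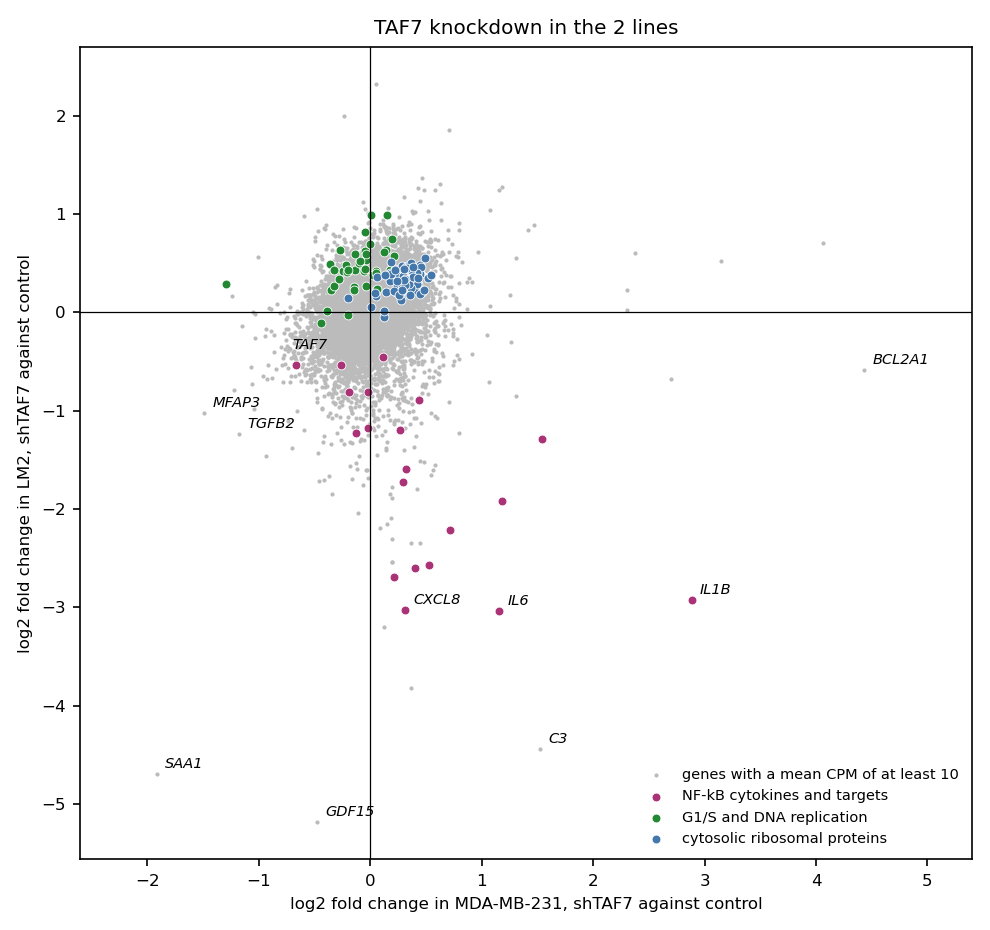
Log2 fold change after TAF7 knockdown in MDA-MB-231 (x axis) and in LM2 (y axis) for the 9412 genes with a mean CPM of at least 10 (grey), with members of NF-kB (purple), G1/S (green) and ribosomal protein (blue) lists. IL1B lies at 2.88 in MDA-MB-231 and -2.92 in LM2, and TGFB2 at -1.18 and -1.24.

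The interaction test asked which genes responded differently to TAF7 knockdown in the 2 lines. IL1B rose in MDA-MB-231 and fell in LM2, a difference of -5.81 ± 0.13 on the log2 scale (edgeR adjusted p = 5.25e-36), and the responses of C3 (-5.97 ± 0.64), BCL2A1 (-5.01 ± 0.33) and IL24 (-4.80 ± 0.62) were also lower in LM2. The responses of PCDH7 (2.42 ± 0.22) and APLN (1.71 ± 0.26) were higher in LM2. CCNE2, which fell in MDA-MB-231, differed by 1.59 ± 0.20.

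As lists, NF-kB cytokines and targets differed by a median of -2.58 (21 of 23 lower and 2 not called, 22 lower adjusted over the list alone) and interferon-stimulated genes by -1.07 (23 of 34 lower and 11 not called, 26 lower adjusted over the list alone). Both calls held with an estimated correlation (adjusted p = 0.00573 and 0.0126). In the first list IL1A differed by -5.40 ± 0.40, CCL20 by -4.38 ± 0.41 and IL6 by -4.19 ± 0.39, and in the second IFIT2 by -2.28 ± 0.14, OASL by -2.16 ± 0.20 and IFIH1 by -2.08 ± 0.20. G1/S and DNA replication genes differed by a median of 0.57 (33 of 40 higher, 37 adjusted over the list alone, camera adjusted p = 4.3e-21, adjusted p = 0.0794 with an estimated correlation), with MCM5 at 0.98 ± 0.10 and CLSPN at 0.91 ± 0.10. Cholesterol biosynthesis genes differed by 0.58 (19 of 25 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 1.4e-12, adjusted p = 0.0735 with an estimated correlation), with IDI1 at 1.19 ± 0.10 and SQLE at 0.97 ± 0.14. YAP/TEAD targets differed by 0.34 (14 of 23 higher, 15 adjusted over the list alone, camera adjusted p = 3.0e-06, adjusted p = 0.0938 with an estimated correlation). Ribosomal protein genes had a median difference of 0.02 and were not called (camera adjusted p = 0.796). Camera called them higher without LM2 shTAF7 replicate 2 (median 0.14). They were also called higher with GC and length offsets (median 0.16, camera adjusted p = 0.0185, adjusted p = 0.725 with an estimated correlation). Neither of these 2 calls held with an estimated correlation.

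Further lists with a lower response in LM2 were ATF4 and amino acid response (23 of 31 lower and 3 higher, also adjusted over the list alone, median -0.66, camera adjusted p = 7.7e-14, adjusted p = 0.0735 with an estimated correlation) and histones (8 of 15 lower, also adjusted over the list alone, median -1.28, camera adjusted p = 9.5e-05, adjusted p = 0.0735 with an estimated correlation). CTH (-2.50 ± 0.16) and DDIT3 (-1.38 ± 0.20) were in the first of these. MHC class I presentation (12 of 18 lower and 2 higher, median -0.51), the lung metastasis signature (9 of 19 lower and 2 higher, median -0.33) and mesenchymal markers (11 of 25 lower and 4 higher, median -0.33) had the same counts adjusted over the list alone. Their camera adjusted p-values were 0.000159, 0.00105 and 0.00844 (adjusted p = 0.262, 0.251 and 0.247 with an estimated correlation), and PSMB9 (-1.86 ± 0.23), KYNU (-1.08 ± 0.11) and COL6A1 (-1.13 ± 0.10) were among their members. Matrix proteases (12 of 28 lower and 3 higher, 12 and 5 adjusted over the list alone, median -0.34) and integrins (4 of 14 lower and 1 higher, 7 and 1 adjusted over the list alone, median -0.36) both had a camera adjusted p of 0.00766 (adjusted p = 0.251 and 0.262 with an estimated correlation). ADAMTS12 (-2.16 ± 0.54) and ITGA1 (-1.31 ± 0.16) were among them. Immediate early genes (11 of 27 lower and 5 higher, median -0.36) and endothelial and fibroblast markers (3 of 5 lower, median -1.30), with the same counts adjusted over the list alone, had camera adjusted p-values of 0.00992 and 0.015 (adjusted p = 0.117 and 0.166 with an estimated correlation). MAPK output (9 of 27 lower and 4 higher, 9 and 5 adjusted over the list alone) had a median of -0.06 (camera adjusted p = 0.0283, adjusted p = 0.426 with an estimated correlation). With GC and length offsets its median turned to 0.04, below the median of all genes (0.10), and camera still called it lower (adjusted p = 0.0401). The list lost its call without MDA-MB-231 control replicate 2, MDA-MB-231 shTAF7 replicate 2 (median 0.01), LM2 control replicate 3 or LM2 shTAF7 replicate 3. The call was also lost without the low-count filter (camera adjusted p = 0.0572). Basal markers (6 of 13 lower and 1 higher, also adjusted over the list alone, median -0.44, camera adjusted p = 0.0292, adjusted p = 0.263 with an estimated correlation) lost theirs without MDA-MB-231 control replicate 2 (0.0582), MDA-MB-231 shTAF7 replicate 2 (0.0623) or LM2 shTAF7 replicate 3 (0.116) and with limma on FPKM (0.127).

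Further lists with a higher response in LM2 were G2/M and mitosis (25 of 39 higher and 1 lower, 27 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 1.6e-10, adjusted p = 0.0938 with an estimated correlation), with ANLN at 0.98 ± 0.10 and MKI67 at 0.68 ± 0.11. Ribosome biogenesis and MYC targets (21 of 32 higher and 1 lower, 23 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 1.1e-09, adjusted p = 0.107 with an estimated correlation) included UTP20 at 0.93 ± 0.10. Heat shock proteins (10 of 22 higher, also adjusted over the list alone, median 0.21) and splicing factors (14 of 36 higher and 4 lower, 17 and 5 adjusted over the list alone, median 0.23) had camera adjusted p-values of 0.000139 and 0.00139 (adjusted p = 0.286 and 0.315 with an estimated correlation), with HSPA8 at 1.13 ± 0.13. General transcription factors (9 of 28 higher and 2 lower, also adjusted over the list alone, median 0.19, camera adjusted p = 0.0179, adjusted p = 0.46 with an estimated correlation) included POLR2B at 0.46 ± 0.10 and lost the call without LM2 shTAF7 replicate 3 (0.0505) and with limma on FPKM (0.0782). Oxidative phosphorylation (7 of 45 higher, 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.0292, adjusted p = 0.668 with an estimated correlation) lost it without LM2 control replicate 3 (0.0789) or LM2 shTAF7 replicate 3 (0.263) and with limma on FPKM (0.138). Common reference genes (8 of 24 higher and 2 lower, also adjusted over the list alone, median 0.09, camera adjusted p = 0.0283, adjusted p = 0.46 with an estimated correlation) lost it without LM2 shTAF7 replicate 3 (0.06) and with limma on FPKM (0.152), where the median was -0.02. The lists not called were TFIID subunits, epithelial and luminal markers, p53 targets, apoptosis regulators, ER chaperones, hypoxia and glycolysis, mitochondrially encoded mRNAs, TGF-beta targets and NRF2 targets. Of these, the mitochondrially encoded mRNAs were called lower without MDA-MB-231 shTAF7 replicate 2 (0.0123) and the NRF2 targets higher without LM2 shTAF7 replicate 2 (0.0248) and without the low-count filter (0.0159). TFIID subunits were called higher without the low-count filter (0.0234).

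In all, 2221 genes had a higher and 1892 a lower response in LM2 at an edgeR adjusted p under 0.05, of which 104 and 709 differed at least 2-fold. The response was higher for 998 genes with limma on FPKM and for 3744 with GC and length offsets. The share of calls that were higher was 54.0%. It was 32.3% with limma on FPKM, where the median shift of a gene from the main fit was -0.098. With GC and length offsets the share was 70.6%, with a median shift of 0.10. Camera called 23 of 34 lists, 10 higher and 13 lower, and only 2 remained called with estimated correlations (10 at an unadjusted p under 0.05 and 24 by fry). The median of a called list in the interaction moved more than 1.5 times without MDA-MB-231 control replicate 3 for MAPK output (-0.0902). Without MDA-MB-231 shTAF7 replicate 2 it moved so for MHC class I presentation (-0.33), heat shock proteins (0.39), immediate early genes (-0.18) and MAPK output (0.0144). Without MDA-MB-231 shTAF7 replicate 3 it moved so for MAPK output (-0.0896). Without LM2 control replicate 2 it moved so for MAPK output (-0.12). Without LM2 shTAF7 replicate 2 it moved so for oxidative phosphorylation (0.26), immediate early genes (-0.19), MAPK output (-0.0299) and common reference genes (0.17). Without LM2 shTAF7 replicate 3 it moved so for oxidative phosphorylation (0.0773). With limma on FPKM the medians in the interaction moved as far for general transcription factors (0.0731), interferon-stimulated genes (-0.48), matrix proteases (-0.22), G2/M genes (0.21), heat shock proteins (0.0941), oxidative phosphorylation (0.005), YAP/TEAD targets (0.19), immediate early genes (-0.23), MAPK output (-0.17), histones (-0.58), splicing factors (0.12), common reference genes (-0.0229), basal markers (-0.13) and endothelial and fibroblast markers (-0.35). With GC and length offsets the medians in the interaction moved as far for general transcription factors (0.33), heat shock proteins (0.34), oxidative phosphorylation (0.30), immediate early genes (-0.23), MAPK output (0.0437) and common reference genes (0.24). Without the low-count filter this held for MAPK output (-0.0304).

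The comparison of the control libraries of LM2 and MDA-MB-231 addressed how the metastatic derivative differs from its parent before any knockdown. IL1B stood at 1064 ± 33.98 CPM in LM2 against 4.99 ± 0.00899 in MDA-MB-231 (log2 fold change 7.74 ± 0.10, n = 2), the granulocyte growth factor CSF3 at 271.4 ± 1.33 against 0.246 ± 0.127 CPM (10.09 ± 0.15), and the collagenase MMP1 at 246 ± 7.97 against 0.332 ± 0.322 CPM (9.54 ± 0.16). MAGEC1, a cancer-testis antigen, had 3055 counts over the MDA-MB-231 controls and none in LM2, at least 496-fold lower against a floor of 3 counts per library. APBB1IP, an adaptor of Rap1 signalling, had 2687 counts in LM2 and none in MDA-MB-231, at least 460-fold higher by the same floor.

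Further genes without a read in the MDA-MB-231 controls were SERPINB9, a granzyme B inhibitor (at least 324-fold higher in LM2), CPPED1 (at least 210-fold), SVIP (at least 192-fold), PPP2R2C (at least 132-fold), C6orf132 (at least 106-fold), NLRP2 (at least 98.9-fold) and IGSF9B (at least 96.5-fold). Genes without a read in the LM2 controls were MAGEA3 (at least 899-fold lower) and MAGEA6 (at least 351-fold), which are near-identical and can share reads, COX7B2 (at least 303-fold), CCBE1 (at least 124-fold), LINC02864 (at least 118-fold), FOXR2 (at least 97.3-fold) and the pseudogene ANKRD20A7P (at least 79.4-fold), whose reads can come from related copies.

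NF-kB cytokines and targets were higher in LM2, with 17 of 23 higher, 5 lower and 1 not called, also adjusted over the list alone. IL6 (7.41 ± 0.17) and the chemokine CXCL3 (4.46 ± 0.13) were among them (median 2.18, camera adjusted p = 3.3e-07, adjusted p = 0.116 with an estimated correlation). Of 34 interferon-stimulated genes, 21 were higher, 5 lower and 8 not called, also adjusted over the list alone, with BST2 at 5.08 ± 0.20 and OAS2 at 3.42 ± 0.25. For interferon-stimulated genes the median was 0.74 (camera adjusted p = 0.0039, adjusted p = 0.212 with an estimated correlation). MHC class I presentation genes were higher in 14 of 18, lower in 3 and not called in 1, also adjusted over the list alone, including PSMB9 (1.56 ± 0.16) and the transactivator NLRC5 (1.30 ± 0.16). For MHC class I genes the median was 0.53 (camera adjusted p = 0.00902, adjusted p = 0.476 with an estimated correlation). Of 31 ATF4 and amino acid response genes, 25 were higher, 1 lower and 5 not called, also adjusted over the list alone, with CTH at 2.81 ± 0.10, JDP2 at 1.97 ± 0.13 and DDIT3 at 1.90 ± 0.13. For ATF4 genes the median was 0.72 (camera adjusted p = 3.2e-07, adjusted p = 0.242 with an estimated correlation). Camera called each of these lists lower with TAF7 knockdown in LM2, although the calls of MHC class I (adjusted p = 0.31) and ATF4 genes (adjusted p = 0.0681) were lost there with an estimated correlation. That comparison shares the LM2 control libraries, so that part of the opposition can come from the chance values of those libraries.

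Of 28 matrix protease and invasion genes, 18 were higher in LM2, 6 lower and 4 not called, also adjusted over the list alone, including ADAMTS12 (6.97 ± 0.23) and ADAMTS6 (2.98 ± 0.12). For matrix proteases the median was 0.60 (camera adjusted p = 0.0036, adjusted p = 0.321 with an estimated correlation). MMP9 had 44 counts in LM2 and 1 in MDA-MB-231, a ratio of 45.2 (95% counting interval 7.70 to 1826). Of 13 basal and myoepithelial markers, 9 were higher, 1 lower and 3 not called, also adjusted over the list alone, with LAMA3 at 3.73 ± 0.12 and COL17A1 at 2.46 ± 0.24 higher and the integrin ITGB4 at -2.82 ± 0.08. For basal markers the median was 0.80 (camera adjusted p = 0.0039, adjusted p = 0.321 with an estimated correlation). Of 27 immediate early genes, 18 were higher, 6 lower and 3 not called, also adjusted over the list alone, with MYC at 2.01 ± 0.07 and FOS at 1.63 ± 0.08. For immediate early genes the median was 0.67 (camera adjusted p = 0.00387, adjusted p = 0.212 with an estimated correlation). Of 27 p53 targets, 16 were higher, 6 lower and 5 not called, also adjusted over the list alone, led by PHLDA3 (2.76 ± 0.34) and GADD45A (2.72 ± 0.08). For p53 targets the median was 0.34 (camera adjusted p = 0.0319, adjusted p = 0.317 with an estimated correlation). All 13 mitochondrially encoded mRNAs were higher, also adjusted over the list alone, with MT-ND1 at 1.11 ± 0.11. For mitochondrially encoded mRNAs the median was 0.55 (camera adjusted p = 0.0039, adjusted p = 0.634 with an estimated correlation).

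In the LM2 controls, 3 lists were called lower. Of 40 G1/S and DNA replication genes, 28 were lower, 7 higher and 5 not called, also adjusted over the list alone, with POLA1 at -1.31 ± 0.08 and MCM7 at -1.14 ± 0.07. For G1/S genes the median was -0.46 (camera adjusted p = 0.000663, adjusted p = 0.476 with an estimated correlation). Of 32 ribosome biogenesis and MYC target genes, 20 were lower, 5 higher and 7 not called, also adjusted over the list alone, with POLR1B at -1.31 ± 0.07 and WDR12 at -1.19 ± 0.07, although MYC was higher. For ribosome biogenesis the median was -0.33 (camera adjusted p = 0.0153, adjusted p = 0.476 with an estimated correlation). Of 22 heat shock proteins, 17 were lower, 3 higher and 2 not called, also adjusted over the list alone, with the chaperones HSPD1 at -1.68 ± 0.07 and HSPH1 at -1.43 ± 0.07. For heat shock proteins the median was -0.35 (camera adjusted p = 0.00387, adjusted p = 0.476 with an estimated correlation). Camera called these 3 lists higher with TAF7 knockdown in LM2. Matrix proteases, basal markers and immediate early genes, higher in the LM2 controls, were called lower there. None of these knockdown calls held with an estimated correlation. That comparison shares the LM2 control libraries, so part of the opposition can come from their chance values. A state of those libraries and an effect of TAF7 cannot be told apart for these lists. Between the controls, the lung metastasis signature had 8 genes higher in LM2, 8 lower and 3 not called, also adjusted over the list alone, and was not called. For the lung metastasis signature the median was -0.01 (camera adjusted p = 0.19), while the mean was 2.05 and fry called the list higher (fry adjusted p = 0.000164). The other lists were not called, but integrins (median 0.64, camera adjusted p = 0.0657) were called higher without MDA-MB-231 shTAF7 replicate 2 (0.0403) or 3 (0.0433), with GC and length offsets (0.0208) and in a fit to only the 4 libraries compared (0.043). Ribosomal proteins (0.17, camera adjusted p = 0.117) were called higher without LM2 control replicate 3 (0.0392), and general transcription factors (-0.18, camera adjusted p = 0.119) lower with GC and length offsets (0.0313). Without the low-count filter camera called 20 lists between the controls. The lists added were integrins (adjusted p = 0.0256) and endothelial and fibroblast markers (0.0385) as higher. Those added as lower were general transcription factors (0.0068), G2/M genes (0.0068), common reference genes (0.0317), TFIID subunits (0.0361), TGF-beta targets (0.0385) and splicing factors (0.0385). None of the calls gained in any of these settings held with an estimated correlation (adjusted p of 0.293 to 0.511 without the filter).

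In all, 5134 genes were higher and 5115 lower in LM2 controls at an edgeR adjusted p under 0.05, of which 2190 and 1314 differed at least 2-fold. With GC and length offsets the median shift of a gene from the main fit was -0.11. None of the 12 lists that camera called was called with estimated correlations (0 lists, against 5 at an unadjusted p under 0.05 and 28 by fry). With limma on FPKM the medians between the controls moved more than 1.5 times for interferon-stimulated genes (0.30), matrix proteases (0.38) and basal markers (0.33). With GC and length offsets the medians between the controls moved more than 1.5 times for heat shock proteins (-0.55) and mitochondrially encoded mRNAs (0.33).

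Lists of markers of other cell types had low medians in every group. Of the 21 luminal markers, only 7 to 9 lay under 1 CPM in a group. The median of 16 leukocyte markers lay between 0.0292 and 0.152 CPM in the 4 groups. However, LCP1, an actin-bundling protein, stood at 195.7 ± 4.40 CPM in the LM2 control against 24.0 ± 2.04 in the MDA-MB-231 control, and CD74, the invariant chain of MHC class II, at 88.1 ± 0.684 against 0.0780 ± 0.110 CPM. Only 4 of those markers had enough reads to be tested, so the list had no set test. The median of 16 endothelial and fibroblast markers lay between 0.0536 and 0.0836 CPM, and the median of 21 luminal breast cell markers between 2.41 and 4.17 CPM, with the keratins KRT8 and KRT18 at 485.3 ± 16.9 and 284.1 ± 11.4 CPM in the MDA-MB-231 control.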

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

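The test of weaker TAF7 knockdown and the test of culture state in this part were chosen only after the results were seen. A difference between the lines in the response to TAF7 knockdown, by the edgeR interaction test for genes and by camera for lists, singled out all the results here. The response was higher in LM2 for 2221 genes (998 with limma on FPKM and 3744 with GC and length offsets) and lower for 1892, and of 177 genes named in either knockdown 117 differed. TAF7 differed by 0.34. PCDH7 (2.42), STXBP6 (2.23) and APLN (1.71) had higher responses in LM2, and FAT3 passed with an adjusted p of 0.0303. C3 (-5.97), IL1B (-5.81), BCL2A1 (-5.01) and IL24 (-4.80) had lower responses. STXBP6 was not called without LM2 control replicate 3 (edgeR adjusted p = 0.105) or LM2 shTAF7 replicate 3 (0.076), nor FAT3 without MDA-MB-231 control replicate 3 (0.114) or either MDA-MB-231 shTAF7 library (0.0948 and 0.146).

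Among lists called by camera, only NF-kB and interferon-stimulated genes stayed called with an estimated correlation (adjusted p = 0.00573 and 0.0126). The median difference was negative for NF-kB genes (-2.58), endothelial and fibroblast markers (-1.30), histones (-1.28), interferon-stimulated genes (-1.07), ATF4 genes (-0.66), MHC class I presentation (-0.51), basal markers (-0.44), integrins (-0.36), immediate early genes (-0.36), matrix proteases (-0.34), mesenchymal markers (-0.33), the lung metastasis signature (-0.33) and MAPK output (-0.0597). It was positive for cholesterol biosynthesis (0.58), G1/S genes (0.57), ribosome biogenesis (0.43), YAP/TEAD targets (0.34), G2/M genes (0.33), splicing factors (0.23), heat shock proteins (0.21), general transcription factors (0.19), oxidative phosphorylation (0.12) and common reference genes (0.0898). The sign of the median turned for MAPK output with GC and length offsets (0.0437) and without MDA-MB-231 shTAF7 replicate 2 (0.0144), and for common reference genes with limma on FPKM (-0.0229). The median of all genes was 0.10 with these offsets and -0.06 with limma on FPKM, and the directions given by camera did not turn.

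The opposite responses of NF-kB genes were weighed against technical explanations. Whether the weaker knockdown in LM2 plays a part stays open, because the upper 95% bootstrap bound of the LM2 median (-1.18) only restates the opposite direction. Leukocyte RNA in the LM2 controls is unlikely as the source, since the median CPM of 5 leukocyte genes (PTPRC, CD3E, TYROBP, LYZ and CORO1A) was 0.00262% of that of IL1B. Of the 16 leukocyte markers 12 lay under 1 CPM there, but LCP1 and CD74, which were not among the 5, stood at 195.7 and 88.1 CPM. A state of the LM2 control libraries alone, such as culture conditions, and an effect of TAF7 that depends on the line cannot be told apart, as no value here separates them. Between the shTAF7 libraries of the lines 8 members were higher in LM2 and 12 lower, so that the median of -0.23 (interval -0.90 to 0.55) decides nothing. No second hairpin or independent control was analysed here.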

How the results depend on the processing

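All alternatives but the GC and length offsets were chosen before the data were examined, and the causes of the shifts below were not tested. Limma on FPKM used no TMM factors, which were 1.03 and 1.04 in the LM2 control libraries and 0.960 and 0.935 in LM2 shTAF7. Leaving them out by itself lowers the LM2 fold changes, whose median shift from the main fit was -0.11. Without the low-count filter 435 genes fell in both lines, the correlation between the lines was 0.0116 and 20 lists were called between controls. Fits to only the 4 libraries compared gave a correlation of 0.104. With limma on FPKM, 1893 genes rose in LM2, 998 had a higher response in LM2 and 445 rose in both lines, the correlation was 0.179, TAF7 passed between controls (0.13, adjusted p = 0.0178), and FAT3 reversed in the interaction (-0.29). With a minimum log2 fold change of 1, 141 genes were higher and 77 lower in MDA-MB-231, 120 and 844 in LM2, 2190 and 1314 between controls, 104 and 709 in the interaction, and 4 and 16 in both lines. With estimated correlations 0, 2, 0 and 2 lists were called in the order of the comparisons, and fry called 28 between controls. With GC and length offsets, chosen after seeing the data, TAF7 between controls turned to -0.0761 (edgeR adjusted p = 0.254), 3744 genes had a higher response in LM2 and 341 fell in both lines. These offsets also rescaled the libraries, so the changes are not those of GC content and length alone.

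With a library left out, the lone sample of its group is assumed to vary like the other groups. MDA-MB-231 then had 897 to 2020 genes higher and 1088 to 2388 lower, 427 to 1047 rose and 368 to 732 fell in both lines, the correlation was -0.0324 to 0.0937, and TAF7 in the interaction was 0.33 to 0.39, with an edgeR adjusted p of 0.0513 without MDA-MB-231 control replicate 3. Replicate numbers did not pair libraries (r of deviations -0.0618 to 0.0214 between groups), and a replicate block gave 2015 higher and 2038 lower genes in MDA-MB-231. Of 5865 alternative values for 399 results of named genes, 5641 kept the side of the threshold, 193 were weaker, 30 stronger and 1 reversed. Direction was compared only for the 361 results called in the main fit, so a turned sign of an uncalled result was not counted. Depth limits genes near 1 CPM, where 1 read is at most 0.0583 CPM.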

Other observations

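In this part the 2 tests of copy number were chosen after the results were seen. The corrections for GC content and length were chosen after the shifts were seen, but before the corrected values were. Camera called ribosomal protein genes higher in both knockdowns (62 of 77 in MDA-MB-231 and 66 in LM2), calls that were lost with an estimated correlation (adjusted p = 0.635 and 0.351). Trends with GC content, transcript length and expression level were weighed as technical sources. After correction for GC and length the lower 95% bootstrap bound of the median was 0.19 in MDA-MB-231 and 0.37 in LM2, above 0.158 and 0.165, which are 50% of the uncorrected medians. The correction also rescaled the libraries, and over all genes the median shift of a gene was -0.017 in MDA-MB-231 and 0.087 in LM2. Random lists matched on expression reached the median of the list in 0 of 10000 draws in MDA-MB-231 and in 53 of 10000 in LM2, where the random lists had a median of 0.23. Most of the LM2 value could therefore follow the trend with expression level. No biological explanation was tested, and reads shared with pseudogenes were not tested.

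Neighbouring genes shifted together in windows of 40 genes. Before correction for GC and length the SD of window medians was 0.0840 in MDA-MB-231, 0.0987 in LM2 and 0.360 between controls. The means of the shuffles were 0.0486, 0.0648 and 0.113. After correction the SD was 0.0580, 0.0825 and 0.359 in the same order, above the highest of the shuffles (0.0471, 0.0696 and 0.134). These trends alone thus do not account for the shifts. In MDA-MB-231 the corrected SD came nearer to the mean of its shuffles (0.0404), so they can account for part of the shifts there. Between the lines the window medians of control and shTAF7 libraries correlated with r 0.955. The uncorrected shifts between the lines far exceeded those of the knockdowns (SD 0.360 against 0.0840 and 0.0987), so a high r was bound to follow. Any lasting difference between the lines would give it, so the value does not single out copy number. For copy number differences between control and shTAF7 populations, the highest window of chromosome 22 in MDA-MB-231 lay at -0.0844 relative to all genes and the end of chromosome 7 in LM2 stood 0.124 above its other windows, and neither value told this explanation apart from others. No biological explanation was tested for the knockdown windows.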
